A study of Homo sapiens with 4 samples.

How the data were processed

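Polyadenylated RNA of HCT116 cells was sequenced as paired-end libraries, per the labels' protocols, in 4 samples of 1 library each: TTC22V1 plasmid (2 µg), empty vector (2 µg), 3 pooled TTC22 siRNAs (100 nM in all) and scrambled siRNA (100 nM). The submitters' processing notes name the aligner STAR, without a version, and the genome build hg38. The program that computed the values, its gene annotation, its strand setting and its filters are not given in the sources used here. The deposited tables, 1 per experiment, hold values that are taken to be FPKM, fragments scaled to gene length and library size, as made by the authors. The unit is inferred, since the headers name none: the values are not whole, they sum to between 181102 and 205734 per library, and the lowest values of genes with a single transcript, times gene length, tend to fall on a common step within a library. Between 17.4 and 19.7% of such values came within 0.02 of a whole number of steps. The step was set at the peak of these same values, so values at the peak count as whole steps by construction. No rate for values without a step was computed. Neither counts nor fold changes were used, as the tables hold none. The depth of each library is unknown, and the relative depths that the steps give lie between 1 and 1.12. The step was sought within the same bounds in all libraries, which limits how far these depths can differ. No counting interval could be given.

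FPKM values are scaled to library size, so a transcript that takes a large part of the fragments lowers the values of all others. TTC22 made up 12.8% of the summed FPKM of the overexpression library. That is a share of length-scaled values, and its share of fragments was not computed. Folds centred on the median of measured genes were therefore set beside the unscaled folds. A gene that the quantification lost in a library can appear as an exact 0. Some genes with under 4 exons stood near 0 in a library without reaching it, such as YWHAG at 0.0527 FPKM in vector and 84.1 FPKM in knockdown. Such low values may also stem from the quantification, which was not tested. For genes listed at 0 the library values are given without a fold. A pseudocount of 1 FPKM was added before log2 was taken, which understates the change of low genes.

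For effects of treatment, each treated library was compared only with the control of its own experiment. Comparisons across the experiments were added after the data had been seen and describe the libraries only. Genes with a mean of at least 1 FPKM over the pair were called measured. A log2 fold of at least 1 in size, which is 2-fold, was the rule of size that took the place of a test, since 1 library per group allows none. This design, 22 gene lists and the rule for named genes were written before the data were examined. The design also foresaw a branch for counts, which was not needed. TTC22, WTAP, SNAI1 and RPL4 are always named, the last 3 from recollection of published work on TTC22 and not from the labels. Also named are the 8 highest and 8 lowest genes past the size rule with a mean of at least 5 FPKM, up to 4 members of each list with the largest folds, and 6 genes for each pair of directions in the relation of the comparisons. The list median was ranked among 10000 random lists of the same size, matched in 20 bins of mean level, with the seed 22. Lists with fewer than 3 measured members were not called, which left 40 medians. Percentiles describe these libraries and are not p-values. Members of a list can vary together, so lists may leave the range more often than the 5% that chance gives for random genes.

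Several choices were made after the data had been seen: the split at 4 exons, leaving out genes listed at 0, the second ranking of named genes with 4 or more exons and no 0, the central 95% of random lists as the range for a list median, the factor of 1.5 beyond which a count is said to have moved, a list of 32 squamous and basal epithelial genes, and the cut-offs of 4-fold and 8-fold for genes of particular libraries. Exon numbers are those of the transcript with most exons in GENCODE 44, which held 91.6% of the gene identifiers in the tables and 99.6% and 99.5% of the genes measured in the plasmid and siRNA comparisons. Coordinates are from the same annotation on hg38. Of the rows in the tables, 2844 had no symbol and were not named, nor were genes with clone-based names.

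The alternatives were a pseudocount of 0.1, median-centred folds, no filter, a mean of at least 5 FPKM, sizes of 1.5-fold and 4-fold, the mean of list members in place of the median, and leaving out TTC22. The scripts were tested on simulated data built from the levels of each comparison. Of 100 genes with a known log2 change of 1.5, 94% passed the size rule in the simulated plasmid comparison and 97% in the simulated siRNA comparison, and of 100 with 2.5 all did. Unchanged genes passed in 0.0395% and 0% of cases. The changed genes were drawn from those at 5 FPKM or more in the control library. The same noise was given to every gene at every level. Its SD, 0.288 and 0.263 on the log2 scale, came from the central spread of the folds. The low rates for unchanged genes follow from that setting. The folds of all measured genes had a wider SD, 0.575 and 0.573. The figures hold for the noise simulated only. They do not hold for quantification noise or for biological variation, which the data cannot give. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.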

Results

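Gene expression was measured by RNA sequencing in HCT116 cells, an established human colon cancer cell line, after TTC22 had been raised or lowered. TTC22 encodes a protein with tetratricopeptide repeats, short motifs that bind other proteins. There were 4 libraries and 4 groups, with 1 library in each group. In the plasmid experiment cells received a plasmid encoding TTC22V1 or the empty vector, and in the siRNA experiment they received 3 pooled siRNAs against TTC22 or a scrambled siRNA. RNA was taken 48 hours after transfection. Each library listed FPKM values for 47251 genes, with sums of 188638 for overexpression, 192908 for vector, 205734 for knockdown and 181102 for scramble. The number of sequenced reads was unknown. With 1 library per group no difference below has a replicate error or a test, and each value describes these libraries only. A gene was called higher or lower if its mean level in the compared pair was at least 1 FPKM and its log2 fold, on the log2(FPKM + 1) scale, was at least 1 in size.

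TTC22 itself (ENSG00000006555, chromosome 1, 54779712 to 54801323 on the minus strand of hg38, with up to 7 exons) was examined first. It was at 24215 FPKM in the overexpression library and 4.46 FPKM in the vector library, a log2 fold of 12.11. TTC22 alone made up 12.8% of the summed FPKM of the overexpression library, which is not its share of fragments. In the siRNA experiment TTC22 was at 6.54 FPKM after knockdown and 10.7 FPKM with the scrambled siRNA, a log2 fold of −0.63 that did not reach the size rule. The knockdown library therefore still held 0.613 of the TTC22 level of its control. The vector library, with its 4.46 FPKM, lay below the knockdown library.

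The plasmid comparison asked which transcripts differ when TTC22V1 is overexpressed. Among genes with 4 or more exons, a mean of at least 5 FPKM and no 0 in either library of the pair, the highest after TTC22 were ERRFI1, a feedback inhibitor of the EGF receptor, at 232 against 26.8 FPKM, and GALNT1, an enzyme that starts O-linked glycosylation, at 10.1 against 0.342 FPKM. ID2, a dominant-negative helix-loop-helix factor, was at 33.6 against 3.99 FPKM. In the scramble library, the control of the siRNA experiment, ERRFI1, GALNT1 and ID2 stood at 662, 3.25 and 51.7 FPKM. A low vector library can therefore not be told from a rise with TTC22V1. CCND1 (cyclin D1) was lower by log2 fold, at 15.4 against 117 FPKM (−2.85). EREG, which encodes the EGF receptor ligand epiregulin, was at 14.9 against 85.4 FPKM (−2.45), and TMED10, a cargo receptor of the early secretory pathway, at 8.24 against 48.6 FPKM (−2.42). The basal keratins KRT14 (0.0663 against 41.7 FPKM), KRT5 (0.0227 against 15.3 FPKM) and KRT6A (0.259 against 14.99 FPKM) were lower too. These keratins stood at 22.7, 15.6 and 14.9 FPKM in the knockdown library and at 0.111, 0.00767 and 0.334 FPKM in the scramble library.

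In all, 212 of 10191 measured genes were higher and 418 were lower with overexpression. The median log2 fold of all measured genes was −0.21, and after centring on it 269 genes were higher and 290 lower. Without TTC22, the summed FPKM was 164423 in the overexpression library and 192903 in the vector library. Genes with few exons weighed heavily in these counts: 24.2% of the 893 measured genes with under 4 exons passed the size rule, against 4.43% of the 9257 with 4 or more, of which 127 were higher and 283 lower. Also among the 8 highest with 4 or more exons and no 0 were PNRC2 (25.8 against 3.27 FPKM), ADNP2 (9.57 against 0.770 FPKM) and NFE2L3 (11.7 against 1.40 FPKM). In scramble PNRC2, ADNP2 and NFE2L3 stood at 15.2, 11.4 and 1.92 FPKM. Among the 8 lowest were also DBNDD1 (1.89 against 17.1 FPKM) and PPAN-P2RY11 (1.45 against 13.7 FPKM), a readthrough gene that overlaps its neighbours and is uncertain for that reason.

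Most genes in the ranking fixed beforehand, over all exon numbers, had under 4 exons. After TTC22 its highest genes were ADIRF (4 exons, 180 FPKM, listed at 0 in vector), SF3B5 (105 FPKM, listed at 0 in vector), COX8A (149 against 2.26 FPKM), SMIM3 (37.4 against 0.338 FPKM) and DPM3 (22.2 against 0.184 FPKM). SNHG19 (15.7 FPKM) and RRS1 (15.6 FPKM) were listed at 0 in vector. Of its lowest genes, RHOB, TSPYL1, IRF2BP1 and SOX4 were listed at 0 in the overexpression library and stood at 84.3, 30.4, 18.4 and 17.6 FPKM in vector. The others were KRT14, SFN (8.16 against 274 FPKM), FADD (0.0225 against 22.4 FPKM) and PPP1R15B (0.139 against 20.6 FPKM). COX8A, SMIM3, DPM3, FADD and PPP1R15B have under 4 exons, and their low values may stem from the quantification, so their directions are uncertain. SFN, which encodes the 14-3-3 sigma protein and has 1 exon, was at 262 FPKM in the knockdown library and 8.66 FPKM in scramble.

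The gene lists fixed beforehand are given relative to the median of −0.21. Of 11 measured heat shock genes, 2 were higher and 0 lower, and the list median was 0.15, which is 0.36 relative to all genes and at percentile 99.97 of random lists of the same size and level, though the mean of its members lay inside the central 95%. The 2 were the chaperone genes HSPA1A (170 against 42.7 FPKM) and HSPA1B (332 against 89.0 FPKM), near-identical copies with 2 and 1 exons whose reads cannot be assigned with certainty. HSP90AA1 was at 491 against 337 FPKM and DNAJB1 at 38.8 against 27.0 FPKM. In scramble HSPA1A, HSPA1B, HSP90AA1 and DNAJB1 stood at 144, 293, 175 and 77.7 FPKM. Of 18 hypoxia and glycolysis genes none passed the size rule, and 15 lay above the median of all genes. Their list median was 0.06, or 0.27 relative to all genes and at percentile 99.95, and their mean was −0.01, or 0.20 relative to all genes, inside the central 95%. P4HA1 stood at 65.0 against 48.1 FPKM and PFKFB4 at 9.47 against 14.5 FPKM. These 2 of 20 list medians lay outside the central 95% of random lists, where chance alone would put 1.

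Of the 9 m6A writers, which add or guide the RNA mark m6A, 0 were higher and 2 lower, of which 1 stayed lower after centring. METTL3, the catalytic subunit, was at 2.84 against 6.97 FPKM (log2 fold −1.05, or −0.85 relative to all genes, and so not past the rule after centring). In knockdown and scramble METTL3 stood at 2.78 and 2.96 FPKM, so a high vector library cannot be told from a fall with TTC22V1. RBM15B, with 1 exon, was listed at 0 in the overexpression library and at 9.61 FPKM in vector. That 0 may stem from the quantification, so a lower level is uncertain. WTAP, the adapter subunit (ENSG00000146457, chromosome 6, 159725585 to 159756319), was at 7.01 against 8.86 FPKM, a log2 fold of −0.30 or −0.09 relative to all genes. None of 12 m6A erasers and readers passed the rule. IGF2BP3 was nearest to it, at 3.35 against 7.66 FPKM. SNAI1 (ENSG00000124216, chromosome 20, 49982980 to 49988886), a repressor of E-cadherin, was at 5.74 against 9.76 FPKM, a log2 fold of −0.68 or −0.47 relative to all genes. TWIST1, the only other measured member of the 6 EMT transcription factors, was at 1.18 FPKM, a log2 fold of −0.20.

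Of 13 epithelial junction and keratin genes 1 was lower, CLDN1 (0.0453 against 2.00 FPKM), which was at 1.70 FPKM in knockdown and 0.0289 FPKM in scramble. Of 11 mesenchymal and matrix genes 3 were lower and 0 higher. They were TGFBI (0.0473 against 3.34 FPKM), THBS1 (1.04 against 5.30 FPKM) and the membrane protease gene MMP14 (0.818 against 3.14 FPKM, within the rule after centring). TGFBI and THBS1 were also at 3.04 and 5.24 FPKM in knockdown and at 0.0419 and 1.04 FPKM in scramble. Of 19 interferon-stimulated genes 2 were lower, IFIT5 (0.00914 against 3.29 FPKM) and IFIT3 (0.932 against 3.38 FPKM), the latter not after centring. Of 7 NF-kB genes RELB (6.15 against 13.8 FPKM) and TNFAIP3 (1.46 against 4.04 FPKM) were lower, and neither passed after centring. Of 7 Wnt target genes CCND1 and ZNRF3 (1.44 against 3.98 FPKM) were lower, the latter not after centring.

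Of 20 ATF4 and unfolded protein response genes TRIB3 was higher (34.6 against 12.8 FPKM), while ATF4 (55.8 against 163 FPKM) and DDIT3 (11.9 against 37.9 FPKM) were lower. The list median was −0.08 and turned to 0.12 relative to all genes. Of 20 cholesterol synthesis genes IDI1 was higher (14.0 against 5.34 FPKM) and DHCR7 lower (11.7 against 31.0 FPKM). Among 47 large ribosomal subunit proteins RPL29 was higher (401 against 159 FPKM), and RPL4 (ENSG00000174444, chromosome 15, 66498015 to 66524532) was at 371 against 437 FPKM, −0.24 or −0.03 relative to all genes. Among 32 small subunit proteins RPS15 was lower (80.0 against 268 FPKM). The ribosomal list medians were −0.24 and −0.27, or −0.03 and −0.06 relative to all genes. Ribosomal protein genes have many processed pseudogenes, so single members are uncertain. EGR1 (41.7 against 95.5 FPKM) was lower among 16 immediate early genes and AEN (8.92 against 19.0 FPKM) among 19 p53 targets, neither after centring, where TNFRSF10B (15.6 against 7.48 FPKM) became higher. No member passed the rule among 18 G1/S genes (median −0.13 relative to all genes), 20 G2/M genes (0.00 relative), 23 TTC family genes (−0.09, or 0.12 relative), 3 mitochondrially encoded genes, or the 2 measured markers of other cell types, CD68 (5.76 against 6.34 FPKM) and COL1A1 (1.82 against 2.99 FPKM).

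**Figure D1:**
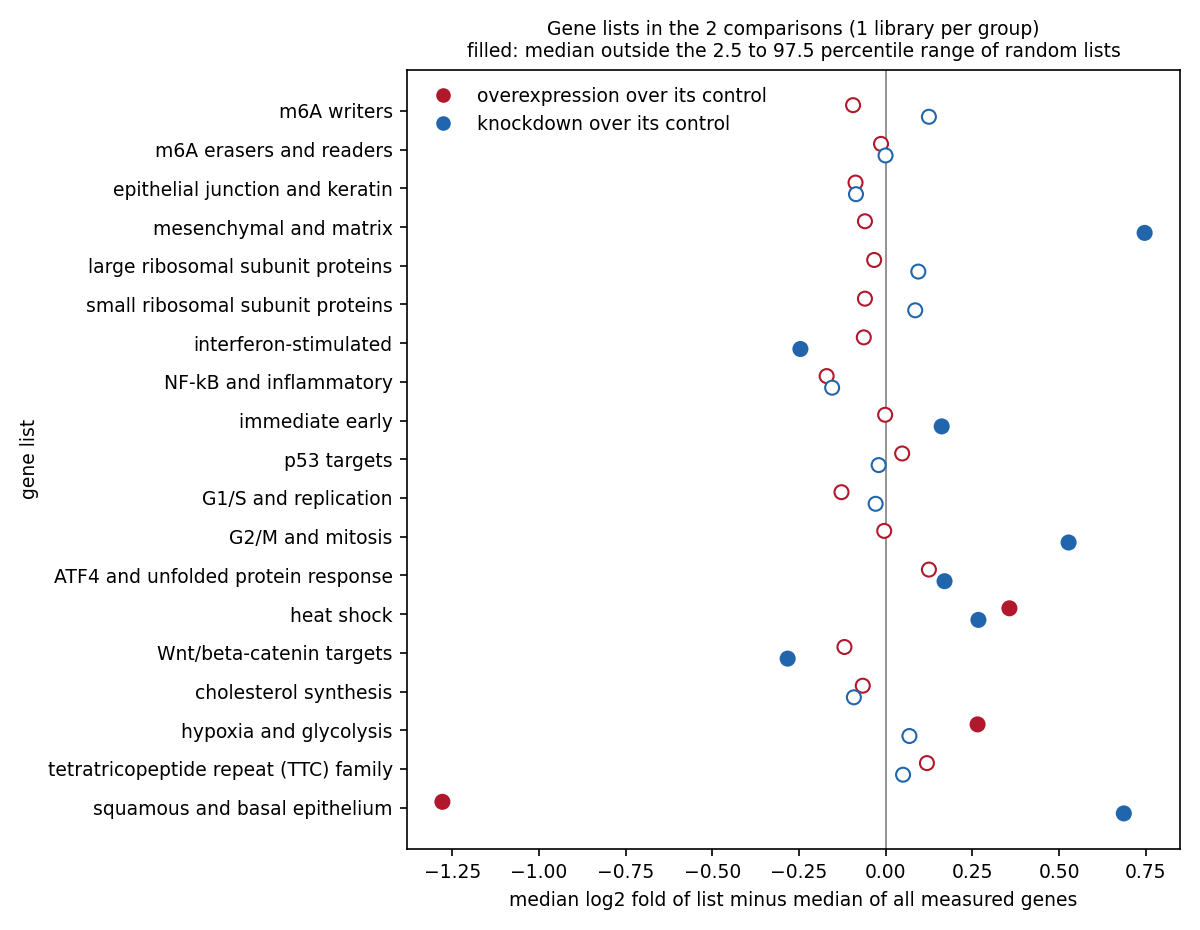
Median log2 fold of the gene lists shown minus the median of all measured genes (horizontal axis, log2 units), with 1 library per group. Overexpression over vector is red and knockdown over scramble blue. Filled points lie outside the central 95% of random lists. The lists of TTC22 and partners, mitochondrially encoded proteins, EMT factors and markers of other cell types are left out. Of these, the mitochondrial list with knockdown lay outside the range, at 4.87. The G2/M list sits at 0.53 in the knockdown comparison and near 0 in the overexpression comparison, and the squamous list, which was added after the data were seen, lies at −1.28 and 0.69.

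The siRNA comparison asked which transcripts differ when TTC22 is lowered. Genes of mitosis were tilted upwards with knockdown: of 19 measured G2/M genes all 19 lay above 0, and 3 passed the size rule. These were the mitotic kinase gene CDK1 (8.74 against 3.38 FPKM), the spindle checkpoint kinase gene TTK (4.51 against 1.49 FPKM) and TOP2A (7.10 against 2.85 FPKM), while AURKA stood at 8.21 against 3.89 FPKM. The list median was 0.50, at percentile 100 of matched random lists, and no alternative changed its direction. The list lay much further apart between the 2 control libraries, with a median log2 difference of −2.44 for scramble over vector. Of 16 G1/S and replication genes none passed the rule and the median was −0.05, with RRM2 at 5.06 against 7.92 FPKM.

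Lower with knockdown among genes with 4 or more exons and no 0 in either library of the pair were EREG (13.9 against 96.4 FPKM), SCD, the desaturase that makes monounsaturated fatty acids (120 against 756 FPKM), TMED10 (10.1 against 66.0 FPKM) and CCND1 (25.4 against 142 FPKM). KIAA0040 (3.25 against 25.2 FPKM), ADNP2 (1.74 against 11.4 FPKM), CREG1 (2.68 against 15.6 FPKM) and the readthrough gene FAM47E-STBD1 (0.0350 against 19.9 FPKM) were also among the 8 lowest that were named. Highest by the same rule were KRT14 (22.7 against 0.111 FPKM), KRT5 (15.6 against 0.00767 FPKM), KRT6A (14.9 against 0.334 FPKM) and KRT17 (11.0 against 0.0303 FPKM), which in the vector library stood at 41.7, 15.3, 14.99 and 6.74 FPKM. They were followed by POMGNT2 (10.5 against 0.213 FPKM), S100A2 (16.2 against 2.10 FPKM), TMEM167B (12.4 against 1.77 FPKM) and the beta-tubulin gene TUBB4B (94.5 against 21.4 FPKM).

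In all, 250 of 9744 measured genes were higher with knockdown and 213 lower, and the median log2 fold was −0.02. Of the 839 genes with under 4 exons 19.3% passed the size rule, against 3.33% of the 8860 with 4 or more, of which 151 were higher and 144 lower. The ranking over all exon numbers was led by MT-CO1 (4429 FPKM), ADIRF (170 FPKM), JUNB (151 FPKM), SF3B5 (99.0 FPKM) and MT-ND6 (56.5 FPKM), each listed at 0 in scramble. MT-RNR2 (12882 against 39.5 FPKM), IER3 (399 against 4.37 FPKM) and YWHAG (84.1 against 0.284 FPKM) completed it. MT-RNR2, IER3 and YWHAG have under 4 exons, and their low scramble values may stem from the quantification. At the other end MT-TF was listed at 0 in knockdown and at 1530 FPKM in scramble. IER2 (1.04 against 68.6 FPKM), RNF139 (0.178 against 27.1 FPKM), TOMM6 (2.13 against 54.0 FPKM), RN7SL1 (0.244 against 19.0 FPKM), SOCS3 (1.30 against 31.6 FPKM) and MIR3615 (0.615 against 17.2 FPKM) followed, with FAM47E-STBD1. IER2, RNF139, TOMM6 and SOCS3 also have under 4 exons, and their low knockdown values are uncertain for the same reason.

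Of 10 mesenchymal and matrix genes 5 were higher and 0 lower, and the list median was 0.72, at percentile 100. The 5 were TGFBI (3.04 against 0.0419 FPKM), THBS1 (5.24 against 1.04 FPKM), the collagenase gene MMP1 (5.14 against 1.38 FPKM), CTGF (6.79 against 2.74 FPKM) and CYR61 (45.8 against 21.5 FPKM), the last named after its value was seen. With a mean level of at least 5 FPKM only 5 members were left and the median was −0.03. TGFBI and THBS1 were also high in the vector library, at 3.34 and 5.30 FPKM. Of 18 interferon-stimulated genes 1 was higher, IFIT5 (2.09 against 0.0800 FPKM), which was at 3.29 FPKM in vector and 0.00914 FPKM with overexpression. The list was otherwise tilted downwards, with 15 members below 0, a median of −0.27 at percentile 0.08 (inside the central 95% by the mean), and IFI6 lower (7.54 against 20.1 FPKM). IFI35 stood at 3.15 against 5.42 FPKM and IFIH1 at 4.23 against 6.59 FPKM.

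All 7 measured Wnt target genes lay below 0, with a median of −0.31 at percentile 0.705, although only CCND1 passed the rule and the median lay inside the central 95% with a mean level of at least 5 FPKM. MYC stood at 81.5 against 102 FPKM. Of 20 ATF4 and unfolded protein response genes 1 was higher, HERPUD1 (31.5 against 15.1 FPKM), and the median was 0.15 at percentile 98.95 (inside the central 95% by the mean). The endoplasmic reticulum chaperone gene HSPA5 was at 661 against 385 FPKM, DDIT3 at 49.7 against 27.6 FPKM and SESN2 at 28.9 against 16.5 FPKM. Of 11 heat shock genes 10 lay above 0 (median 0.24, percentile 99.43, inside the central 95% by the mean), but the only one past the rule, HSPB1, was lower (85.8 against 352 FPKM). Of 18 immediate early genes 3 were higher, JUNB, IER3 and SPRY4 (14.3 against 3.62 FPKM), and IER2 was lower. All 4 have under 4 exons. The median of that list was 0.14 at percentile 97.95, and at 95.67 for its 10 members with 4 or more exons. Of 4 measured mitochondrially encoded genes, 3 were higher (MT-CO1, MT-ND6 and MT-CO2, each listed at 0 in scramble) and MT-ND4 was lower (14.3 against 41.7 FPKM). The median of that list, 4.85 at percentile 100, rests on these zeros. In the knockdown comparison 8 of 20 list medians, the mitochondrial list among them, lay outside the central 95% of random lists, where chance alone would put 1.

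WTAP was at 8.36 against 7.21 FPKM with knockdown (log2 fold 0.19), SNAI1 at 5.08 against 5.61 FPKM (−0.12) and RPL4 at 686 against 555 FPKM (0.31). None passed the size rule. Of 8 m6A writers only RBM15B, with 1 exon, passed the rule, listed at 0 after knockdown and at 6.01 FPKM in scramble. That 0 may stem from the quantification, so a lower level is uncertain. The median of the list was 0.10 while its mean was −0.28. METTL3 was at 2.78 against 2.96 FPKM. None of 11 m6A erasers and readers passed the rule, with IGF2BP2 at 26.1 against 39.5 FPKM. Of 12 epithelial genes CLDN3, with 1 exon, was listed at 0 after knockdown and at 4.60 FPKM in scramble. BTG2 (0.279 against 11.7 FPKM) and GDF15 (34.1 against 92.5 FPKM) were lower among 18 p53 targets, and NDRG1 (874 against 421 FPKM) was higher among 19 hypoxia and glycolysis genes. RPL29 (281 against 639 FPKM) was lower among 47 large ribosomal subunit proteins, whose median was 0.07. No member passed the rule among 32 small subunit proteins (median 0.06), 20 cholesterol synthesis genes (−0.12), 8 NF-kB genes (−0.18), 18 TTC family genes (0.03), the 2 measured EMT factors, where TWIST1 was at 1.23 against 1.44 FPKM, or CD68 (37.2 against 42.6 FPKM) and COL1A1 (2.15 against 2.06 FPKM).

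The pair of comparisons, which share no library, was then set side by side over 9226 genes measured in both. Some genes moved in opposite directions. Higher with overexpression and lower with knockdown were, among genes with 4 or more exons and no 0, ADNP2, KIAA0040, AK3 (10.9 against 2.27 FPKM and 3.20 against 15.8 FPKM), TMEM230, PCYOX1 and PPIL1. The reverse held for KRT14, KRT5, KRT6A, KRT17, TGFBI and S100A2. Other genes moved the same way in both. EREG, CCND1, TMED10, ARL6IP5 (5.66 against 24.7 FPKM and 5.33 against 24.3 FPKM), PGRMC2 (2.39 against 10.9 FPKM and 2.20 against 8.99 FPKM) and RAB11A (4.56 against 15.9 FPKM and 6.50 against 28.0 FPKM) were lower in both treated libraries. NUDT4, the nuclear import gene KPNA6 (11.4 against 2.44 FPKM and 10.8 against 3.23 FPKM), ZKSCAN1, WDR45B, WASL and PDCD7 were higher in both.

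Over all exon numbers, RN7SL1, RRS1, INTS5, FAM47E-STBD1, KLHL9 and C6orf226 led the genes higher with overexpression and lower with knockdown. SFN, KRT14, PPP1R15B, KRT5, KRT6A and SDHAF1 led the reverse. ADIRF, SF3B5, SMIM3, NFIL3, IER5 and DPM3 led those higher in both, and RNF139, FAM46B, RBM15B, EREG, CCND1 and TMED10 those lower in both. Many of these calls rest on an exact 0. RN7SL1, RRS1, FAM47E-STBD1, KLHL9 and C6orf226 were listed at 0 in vector, and RRS1, INTS5, KLHL9 and C6orf226 in knockdown. ADIRF, SF3B5 and IER5 were at 0 in vector and scramble, SDHAF1 in overexpression and scramble, and RBM15B in overexpression and knockdown. A 0 may stem from the quantification, so the directions of these genes are uncertain. The same holds for SMIM3, NFIL3, DPM3, PPP1R15B, RNF139 and FAM46B. They have under 4 exons and stood far lower in some libraries than in others, though not at 0. Across genes, which are not independent replicates, the log2 folds correlated at a Pearson r of 0.04 and a Spearman rho of 0.09. In opposite directions 74 genes passed the size rule in both comparisons, 31 of them higher with overexpression and 43 lower. In the same direction 70 did, 31 higher and 39 lower. Independent lists would share 3.81, 7.70, 3.97 and 7.39 genes in these 4 classes. Among genes with 4 or more exons 45 were opposite and 39 the same.

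**Figure D2:**
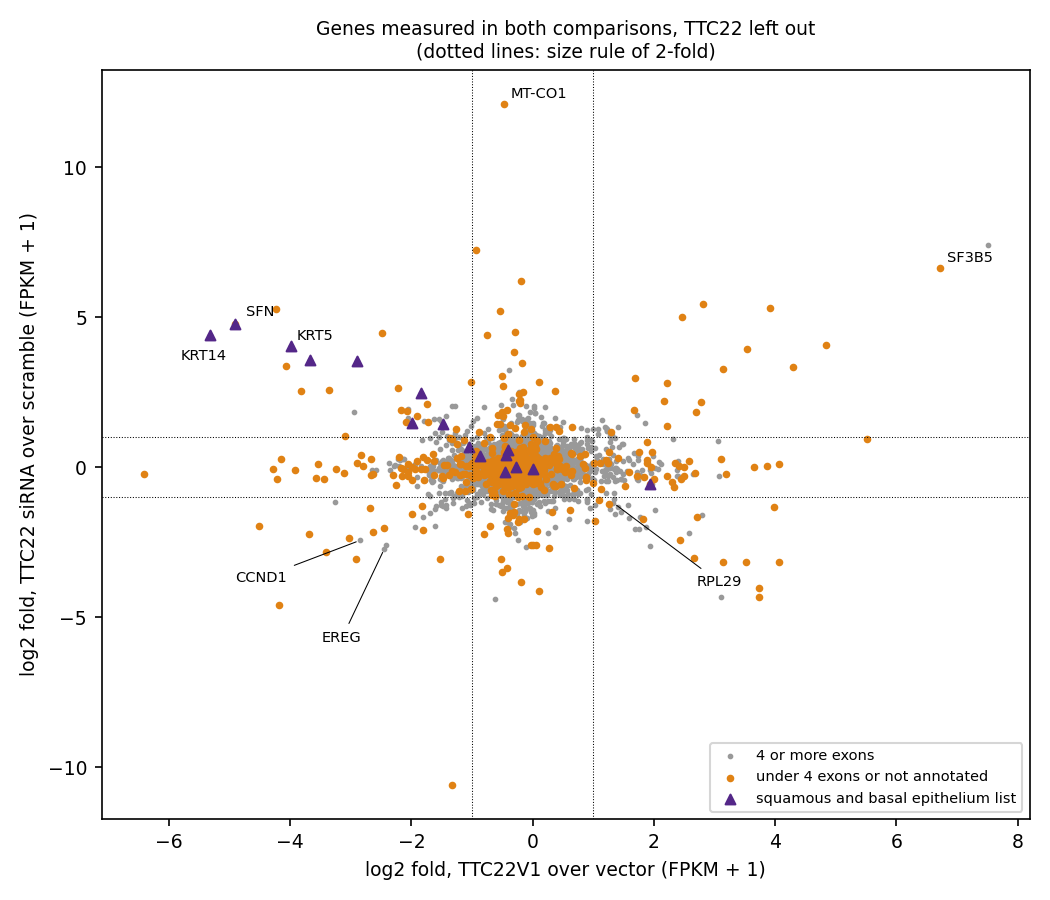
Log2 fold of knockdown over scramble (vertical axis) against log2 fold of overexpression over vector (horizontal axis) for genes measured in both comparisons, without TTC22; each point is a gene on the log2(FPKM + 1) scale, with 1 library per group, and orange points have under 4 exons or no annotation. All 4 corners beyond the dotted 2-fold lines hold genes, 74 in opposite and 70 in the same direction, and the squamous genes KRT14, SFN and KRT5 lie at the upper left.

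The 2 control libraries, which carry no TTC22 treatment, differed from each other more than either treated library did from its control. Between scramble and vector 510 of 10214 measured genes were higher and 1440 lower, across 2 tables whose scaling to each other is not known. Of the keratins of simple epithelia, KRT8 stood at 291, 357, 354 and 300 FPKM in overexpression, vector, knockdown and scramble, KRT18 at 229, 289, 271 and 292 FPKM and KRT19 at 453, 498, 702 and 836 FPKM. KRT7, picked out after its values were seen, was higher in vector and knockdown, at 0.50, 5.27, 4.37 and 0.725 FPKM. KRT17 stood at 0.0412, 6.74, 11.0 and 0.0303 FPKM in the same order.

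**Figure D3:**
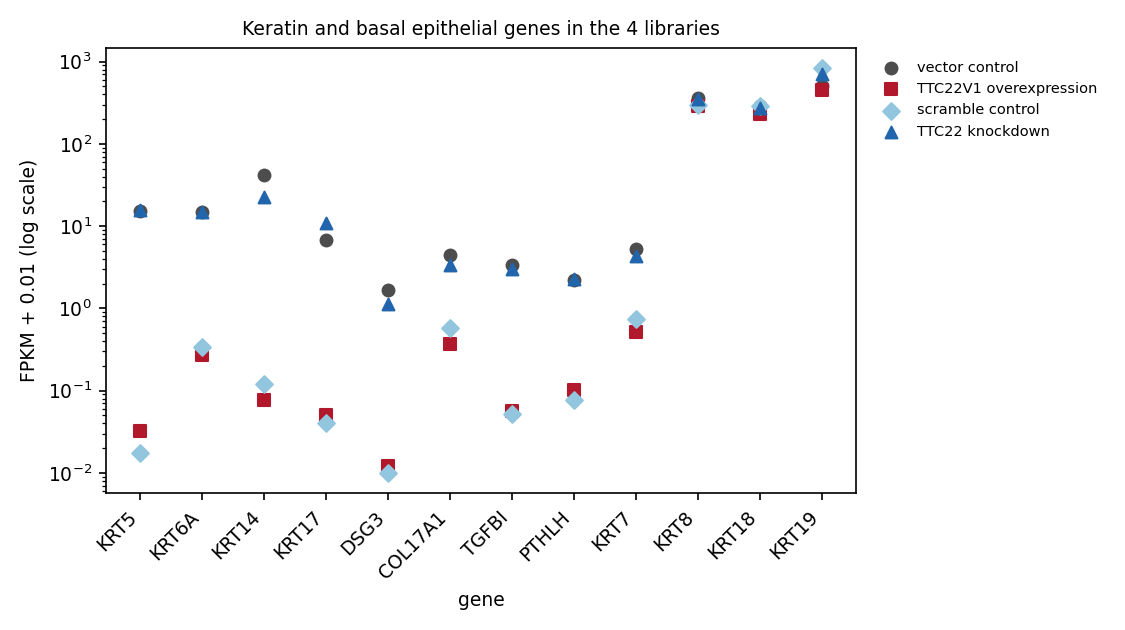
Levels of keratin and basal epithelial genes in each of the 4 libraries (vertical axis, FPKM plus 0.01 on a log scale; 1 point per library). KRT5, KRT6A, KRT14, KRT17, DSG3, COL17A1, TGFBI, PTHLH and KRT7 are high in the vector and knockdown libraries and low in the overexpression and scramble libraries, whereas KRT8, KRT18 and KRT19 do not follow this pattern. The genes shown are a selection made after the data were seen. Of the 32 squamous list genes, 9 met the pattern at 4-fold. KRT15 and KRT16 of that list, not shown, lack it (4.86, 6.80, 21.9 and 14.3 FPKM, and 0.297, 0.344, 1.11 and 1.37 FPKM, in overexpression, vector, knockdown and scramble).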

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

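The alternatives limited to genes with 4 or more exons, with or without centring, to genes not listed at 0, or without squamous genes or list members high in vector and knockdown were chosen after the data were seen; the others were planned. The counts of genes past the size rule moved with the level filter, the size and the exon number, each of which by construction admits other numbers of genes. For overexpression (630), knockdown (463), shared genes in opposite directions (74) and shared genes in the same direction (70), in this order, the counts were 328, 229, 35 and 39 with a mean of at least 5 FPKM, 1452, 1098, 155 and 181 at 1.5-fold, 157, 132, 20 and 22 at 4-fold, 410, 295, 45 and 39 with 4 or more exons, and 352, 296, 48 and 37 with 4 or more exons and centring. A pseudocount of 0.1, no filter, centring alone, and leaving out genes listed at 0 or squamous genes kept these counts within 1.5 times. Of the folds of named genes other than TTC22 and with no 0, 47 moved by more than 1.5-fold or across the size rule with a pseudocount of 0.1 and 188 did not, and 10 moved with centring and 225 did not; none turned in direction where called. Centring took the overexpression split from 33.7% to 48.1% higher. TTC22 kept its direction, between 12.11 and 12.37 with overexpression and between −0.70 and −0.61 with knockdown. The Pearson r of the folds lay between 0.0057 and 0.080 in these alternatives but was −0.0077 among genes with 4 or more exons and no 0, and Spearman rho lay between 0.093 and 0.11.

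Of the 10 list medians outside the percentile range, the G2/M list with knockdown lay between 0.48 and 0.60 in all 10 alternatives. The sign of the uncentred value turned in 2 cases. The hypoxia and glycolysis list with overexpression was −0.010 by the mean, which is 0.20 relative to all genes and inside the range, and the mesenchymal and matrix list with knockdown was −0.028 with a mean of at least 5 FPKM, where 5 members were left. Without a filter the mesenchymal list, with 17 members, was 0.017 and inside the range, and without its members high in vector and knockdown it was 0.26. The cause was not tested. The mitochondrial list with knockdown gave no value with 4 or more exons, with or without centring, or without genes listed at 0, as fewer than 3 members were left. The immediate early list with knockdown was inside the range in 4 alternatives. So were, by the mean of the members, the heat shock lists of both comparisons and the interferon-stimulated and ATF4 lists with knockdown, and, with a mean of at least 5 FPKM, the Wnt list with knockdown. In the other direction, some lists inside the range left it in some alternatives, such as the ATF4 list with overexpression, at percentile 98.05 with 4 or more exons. Not run, since they need counts or deposited folds, were the other count normalizations, the prior count, the counting interval, FPKM in place of counts and the authors' fold. No paired analysis was possible because each group has 1 library, which also rules out leaving a library out. Depth is unknown, so what it limits cannot be stated.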

Other observations

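All tests in this part were chosen after the patterns had been seen, and all but the test by level bins after the result it measures; the gene lists other than the squamous list were fixed before. Between the experiments, cell cycle genes stood far apart. All 20 measured G2/M genes were lower in scramble than in vector, with a median log2 difference of −2.44, and all 20 were lower in knockdown than in overexpression, with a median of −1.69. CCNB1 was at 96.6 and 78.1 FPKM in vector and overexpression and at 10.9 and 15.8 FPKM in scramble and knockdown. Of 18 G1/S genes 17 were lower in scramble than in vector, with a median of −2.03. Hypoxia and glycolysis genes went the other way: 8 of 19 were at least 2-fold higher in scramble than in vector and none at least 2-fold lower, with a median of 0.82. At a 4-fold cut-off 183 genes were higher in the plasmid pair than in the siRNA pair and 62 the reverse. These values cross tables and have no test. Scaling alone would move all lists the same way. The G2/M list and the hypoxia and glycolysis list moved in opposite directions in both pairs, the latter by a median of 1.13 for knockdown over overexpression. That argues against scaling alone for these lists, though it may add to the differences. Transfection and culture cannot be told apart.

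The squamous and basal epithelial genes form the first pattern. Of 32 such genes, none of which is on another list and 8 of which were at 1 FPKM or more in both the overexpression and scramble libraries, 17 were measured in each comparison. With overexpression 10 were lower and 1 higher (median −1.48), and with knockdown 8 were higher and 0 lower (median 0.66). Genes with the pattern include SFN (274 and 262 FPKM in vector and knockdown), KRT14 (41.7 and 22.7 FPKM) and KRT5 (15.3 and 15.6 FPKM). Other list genes lacked it: ITGB4 was at 105, 128, 299 and 300 FPKM and LAMB3 at 16.2, 30.3, 149 and 116 FPKM in overexpression, vector, knockdown and scramble. FGFBP1, the 1 that was higher with overexpression, was at 4.62, 0.469, 12.7 and 19.3 FPKM in the same order. Of squamous differentiation genes, S100A8 was near 0 (0.00471 and 0.0208 FPKM in vector and knockdown). IVL, SPRR1A, SPRR1B, SPRR3, S100A7 and S100A9 were likewise at 0.157 FPKM or below in every library. KRT13 was at 3.06 and 4.72 FPKM in vector and knockdown. CSTA was at 6.92 and 4.67 FPKM there but also at 6.90 and 4.84 FPKM in overexpression and scramble.

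Few exons do not account for it, since 8 of the list genes with the pattern have 4 or more exons. A candidate explanation is RNA or reads of other, basal epithelial cells in the vector and knockdown libraries. Among genes with 4 or more exons, 11 and 19 were found at 8 times the level of any other library in vector and in knockdown alone, TTC22 aside, so the lower count was 11, against at most 2 in the other libraries. They include TP63 (2.08 FPKM in vector), LGALS7 and SERPINB4 (3.25 and 2.47 FPKM in knockdown), but also GINS3 (3.24 FPKM in vector), a replication gene that need not come from other cells. Whether 1 source served both libraries stays open: of the 12 list genes with 4 or more exons that reached 1 FPKM in vector or knockdown, and there at least 4 times the level of overexpression and scramble, only TP63, 1 gene, had a ratio of vector to knockdown over 2 log2 units from the median, and 3 lay over 1 unit from it, both bounds having been tried after the values were seen. Below 1 FPKM, and so not counted, KRT6B was at 0.756 FPKM in vector and 0.0888 FPKM in knockdown. GPX2, which has 3 exons and is not on the list, was at 9.95 FPKM in vector, 0.369 FPKM in knockdown and 0 in the other libraries, and so goes against 1 source. So do LGALS7 and SERPINB4, which are not on the list either and were at 0.0561 and 0.0312 FPKM in vector. They were selected for being high in knockdown alone. Single genes picked out after their values were seen do not settle whether 1 source served both libraries. A response to TTC22 stays open as well, because the libraries with less TTC22 are the same ones that show the pattern. Each group also has 1 library. The 12 genes were selected for being high in these libraries, so they could not argue against it. In knockdown, scramble and overexpression, TTC22 was at 6.54, 10.7 and 24215 FPKM and KRT14 at 22.7, 0.111 and 0.0663 FPKM. Near the floor a further fall of KRT14 could not be seen. The vector library held 0.418 times the TTC22 level of the scramble library. Its KRT5 level was 1989 times that of scramble, which is no measured fold, since KRT5 in scramble amounts to about 1.44 steps of the smallest value.

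The second pattern is genes listed at 0 in a library while at 5 FPKM or more in another. They may come from the authors' quantification losing genes with 1 exon. Of 77 genes with 1 exon, 57.1% were listed at 0 in a library, against 0.0519% of 5781 genes with 4 or more exons. Argued against are too few reads, since the lowest level above 0 in the other libraries predicts a median of 876 steps of the smallest value, and the TTC22 level, since the library with most such zeros had 1.57 times those of the library with fewest (21 in overexpression, 18 in vector, 14 in knockdown and 22 in scramble). The mitochondrial genome fits the same picture: 8, 8, 8 and 12 of its 13 protein genes were listed at 0 in overexpression, vector, knockdown and scramble.

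The third pattern is the excess of genes past the size rule in both comparisons, in all 4 classes of direction. Opposite responses to raised and lowered TTC22 alone would give no excess in the same direction. Yet 31 genes were higher and 39 lower in both, where independent lists would share 3.97 and 7.39. Of the shared genes 51.4% were opposite (exact 95% interval 42.9 to 59.8%, which treats genes as independent), which does not decide whether most were. TTC22 in knockdown was at 0.613 of its control, within the size rule, so that pair could show little response to lowered TTC22. Whether such responses account for part of the opposite genes stays open. Genes with few exons alone are argued against by an excess of at least 5.64 times in each class among genes with 4 or more exons, and low levels alone by at least 5.11 times when independent lists were drawn within 20 bins of level. It also stays open that some genes vary between any 2 libraries, through biology or quantification, which these 4 libraries cannot resolve. No biological explanation beyond the TTC22 level was tested.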
